A study of Arabidopsis thaliana with 32 samples.

How the data were processed

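Transcript levels were measured in 32 samples of Arabidopsis thaliana Col-0 seedlings, each hybridised to its own 1-colour Agilent array with probes for annotated genes and for short open reading frames (sORFs). The labels give 8 exposure times of 4 biological replicates, with replicates 1 and 3 from chamber A and replicates 2 and 4 from chamber B, and all samples mapped to their files with 0 unmapped columns. The file of 12 h replicate 1 carries the number 4 in its name, at odds with its label, and the label was used, so its replicate number and chamber are in doubt. Total RNA was extracted with TRIzol and amplified to Cy3-labelled cRNA from an oligo-dT primer, per the labels' protocols. Images were read with Agilent Feature Extraction 9.5.3.1, with background subtraction and detrending, per the file headers. The deposited files hold for each spot a processed signal, which is a microarray intensity on a linear scale, per the file headers. Agilent Feature Extraction and affy are the tools named, per the submitters' processing notes, without a version there. The deposited series matrix holds normalized intensity for the same arrays. Its 32 columns share a median of 335.1, and within each array its ranks matched those of the processed signal with a lowest rank correlation of 1.0. Its centring beyond this is not stated. Probe coordinates follow the build ath1:Jan2004 named in the headers.

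The array holds 34262 probes, of which 26832 are for annotated genes, 5974 for sORFs and 1456 for other transcripts, and no feature has more than 1 probe. Gene names came from the reference table, which held 26171 of the loci, 10292 of them with a symbol, and otherwise the locus is given. Between 22799 and 26583 probes per array (66.5% to 77.6%) were well above background, and the number of arrays limits the precision of each value.

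From these files, log2 of the processed signal minus the 75th percentile of each array was computed, spots with outlier marks were left out, and features well above background on at least 3 of the 4 arrays of some group were kept. This left 24356 features (22114 annotated, 1184 sORFs and 1058 others). R 4.3.3 with limma 3.58.1 and the package data.table, version 1.17.8, fitted group means over all 32 arrays (lmFit and eBayes, residual df 24, prior df 2.88), and python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots. Each of the 7 exposure times was compared with 0 h, an F test covered the 7 comparisons, and a contrast set the mean of 2 h, 6 h and 12 h against the mean of 3 d, 7 d and 14 d (short minus long exposure). All adjusted p-values are limma's moderated tests with Benjamini-Hochberg adjustment per comparison at 0.05 unless another test is named. Errors of log2 fold changes are standard errors (SE) with n = 4 arrays per group. A gene not well above background on any array of a group has only a bound there, written "at least N-fold", from the brighter group's mean against the higher, per array, of the dim probe's own signal and the lowest signal among probes well above background. For short minus long exposure such a bound is given where the dimmer side has at most 6 of 12 arrays well above background, with each of its arrays raised to that signal.

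Lists of genes were written for 25 themes and tested with camera at its preset correlation of 0.01, adjusted over all 200 tests, and again with the correlation estimated from the residuals. No list call held with the estimated correlation, where the smallest adjusted p was 0.27. The ribosomal list was taken from the array's own gene descriptions. Shares of sORFs and annotated genes were compared with Fisher's exact test and within 5 strata of mean signal. Words of the gene descriptions were tested for enrichment (902 terms), and so were 121 bins of 1 Mb, both over the features tested. The design, the lists, the rule for naming genes and the alternatives were fixed before the data were examined, except for the blocks by scan day and label letter and the settings that leave out slide 1 (alone or with 1 d replicate 3) or the chromosome 2 block. That rule named, per comparison, the 10 largest rises and 10 largest falls among annotated genes past the threshold whose 4 arrays all lay on one side of the 0 h mean (for short minus long, whose 3 time means all lay above or below the other 3) and that were well above background on at least 3 arrays of the higher group. It added up to 3 rises and 3 falls among sORFs, the 10 smallest p-values of the F test, and up to 4 members of each list. The word and position tests and the low-oxygen genes were chosen after the values were seen.

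The steps were tested on simulated data made from the real means and spreads, for the 2 h comparison with 200 of 23423 features changed. A further list of 100 features was shifted slightly as a set and is not counted below. The noise was drawn independently for each feature and array, without slide effects or correlation between genes. The values therefore do not give the rate of false calls in the real arrays. The fit called 16.4% of the features changed 1.5-fold, 59.7% of those changed 2-fold and 86.4% of those changed 3-fold, each in the right direction, with 7 of the unchanged features called as well, and 0 features when none was changed. The arrays lay on 8 slides of 4 arrays and were scanned on 3 days. Slide, scan day, chamber and replicate number were tried as blocks. For 0 h and 14 d the deviations of same-numbered arrays from their group means had correlations of 0.732, 0.392, 0.12 and 0.326, so the numbers may pair the arrays there (numbers 1 and 2 also share a slide), and at each other time at least 1 pair was below 0.1. Other alternatives were the normalization, the background correction, the deposited value table, the filter, array weights, the threshold, the groups in the fit, each chamber alone and each array left out. Control spots were left out of all tests.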

Results

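Arabidopsis Col-0 seedlings were exposed to elevated CO2 (780 μmol/mol) after growth at ambient CO2 (390 μmol/mol), for one of 7 times between 2 h and 14 d, or kept without exposure (0 h). All were sampled at an age of 14 d, which by the labels leaves the 14 d group no time at ambient CO2. They grew at 22 °C with 16 h of light and 8 h of dark per day, per the labels. Each of these 8 groups had 4 arrays, and each array had a single sample. A 75th percentile signal of 1447 to 4232 units per array was measured before scaling. Arrays differed by slide: of the variance of the leading principal component (18.6% of the total), 89.1% lay between slides, 65.9% between scan days and 17.9% between exposure groups. Of the 160 values of named genes, 88 no longer passed the threshold with slide as a block. The question of each comparison was which annotated genes and sORFs had another transcript level after that time at elevated CO2 than in the seedlings kept at ambient CO2. Each time was compared with the same 0 h group and has no ambient control of its own. An effect of the hour of day, at harvest or at the start of exposure, therefore cannot be told apart from that of CO2.

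After 2 h, genes described as mitochondrial, as transducin proteins or as helicases were enriched among those that rose, and light harvesting genes had a lower list median. AT1G02830, described as a ribosomal protein of the large subunit, rose from a level not well above background on any 0 h array to at least 2.68-fold higher (adjusted p = 0.0022, 4 of 4 arrays higher). NUDT24, a Nudix hydrolase, rose by 2.78 ± 0.65 (log2, SE, n = 4, adjusted p = 0.043), with 1 of 4 arrays at 0 h well above background. The mitochondrial carrier DIC2 rose by 1.42 ± 0.32 (adjusted p = 0.035) and the gene AT4G30990, described as binding, by 1.32 ± 0.17 (adjusted p = 0.00066). The thylakoid kinase STN7, which acts in the balance between the photosystems, fell by 1.3 ± 0.27 (adjusted p = 0.023), the antenna protein LHB1B2 fell by 0.87 and the autophagy protein ATG8F fell by 1.02. In all, 137 features rose and 11 fell at 2 h, of 24356 tested. Among the 108 annotated genes that rose, the words mitochondrial (9 of 173), DEAH (5 of 28), transducin (7 of 100) and helicase (7 of 138) were enriched (hypergeometric test, adjusted p = 2e-04, 0.00021, 0.00039 and 0.0026). In the part of chromosome 2 described below, whose features shifted together, 3 genes described as mitochondrial rose. They do not count as independent genes, and the enrichment was not tested without them. Of the 181 cytosolic ribosomal proteins, 3 rose over all features (7 adjusted over the list alone), with a list median of 0.26 (camera adjusted p = 1.2e-13, but p = 0.55 with the estimated correlation). None of the 28 light harvesting and photosystem genes on the list passed over all features, 4 fell adjusted over the list alone, and the list median was -0.39 (camera p = 1.2e-08 and 0.45 with the estimated correlation). Calvin-Benson cycle (-0.20), photorespiration (-0.32) and circadian clock (-0.17) genes had lower list medians and flavonoid genes a higher one (0.31), all called by camera with the preset correlation but not with the estimated one, and with no member past the threshold over all features. With slide as a block 267 features were called at 2 h, 2458 with array weights and 12 without slide 1. The weight was 4.487 for 2 h replicate 2 and 0.616, 0.688 and 0.573 for replicates 1, 3 and 4, so the weighted 2 h mean rests mostly on replicate 2. With only 0 h and 2 h in the fit limma called 0 (2907 with an unadjusted p under 0.05). The count was 42, 45, 35 and 13 without 0 h replicates 1 to 4, and 13, 58, 41 and 245 without 2 h replicates 1 to 4. Between arrays on slide 2, the list medians were 0.35 for ribosomal proteins and -0.44 for light harvesting genes, and on slide 5 they were 0.64 and -0.26. On these slides they were 0.03 and -0.02 for the Calvin-Benson cycle, so its shift was near 0 within slides, -0.18 and -0.22 for photorespiration, -0.02 and -0.35 for the circadian clock and 0.48 and 0.88 for flavonoid genes.

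A larger share of sORFs than of annotated genes was called at 2 h, but 20 of the 22 sORFs called lie in one part of chromosome 2. Without that part the odds ratio turned to the other side of 1. Of 1184 sORFs tested 22 (1.86%) were called, against 119 of 22114 annotated genes (0.538%), an odds ratio of 3.50 (95% interval 2.11 to 5.57, Fisher's exact test, adjusted p = 2.34e-05), and 5.55 within strata of signal. NEW_TU_1519 (chromosome 2, 3430554 to 3430685, build ath1:Jan2004) rose by 1.71 ± 0.34 (n = 4, adjusted p = 0.019), and its neighbour NEW_TU_1724 by 1.59 and NEW_TU_907 by 1.56. Between 3000001 and 4000000 on chromosome 2, 32 of 229 features rose, 20 of them sORFs and 7 annotated genes, more than in the other bins of 1 Mb (hypergeometric adjusted p = 1.4e-32 over 1210 tests). The annotated genes that rose there include AT2G07749 (1.73) and AT2G07773 (1.36), described as identical to mitochondrial proteins, and 21 of the 66 annotated genes of the block carry such a description. The median change of the block was 0.95 at 2 h, 0.63 at 6 h, 0.55 at 12 h, 0.52 at 1 d and 0.33 to 0.37 at 3 d, 7 d and 14 d. At 2 h, 6 h and 12 h replicates 1 and 2 each lay above replicates 3 and 4. Without this block the odds ratio at 2 h was 0.255 and the count of features called at 2 h was 83. Features of the block shifted together (96.9% were above their 0 h mean), and Fisher's exact test treats features as independent. Its p and interval at 2 h are therefore too narrow for a statement on sORFs as a class. Without 2 h replicate 1 the odds ratio was 1.56, and it was also smaller without slide 1 and with no filter. At 6 h, 12 h and 1 d the odds ratios were 1.29, 0.601 and 1.12 (Fisher's exact test, adjusted p = 1 each), and at 1 d it was 2.15 within strata of signal (95% interval 0.926 to 4.51, unadjusted p = 0.0564). With 1 array left out and any features still called, the odds ratio at 1 d ran from 0.344 to 0.979. At 3 d, 7 d and 14 d 0 sORFs and at most 5 annotated genes were called, too few to compare shares.

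**Figure D1:**
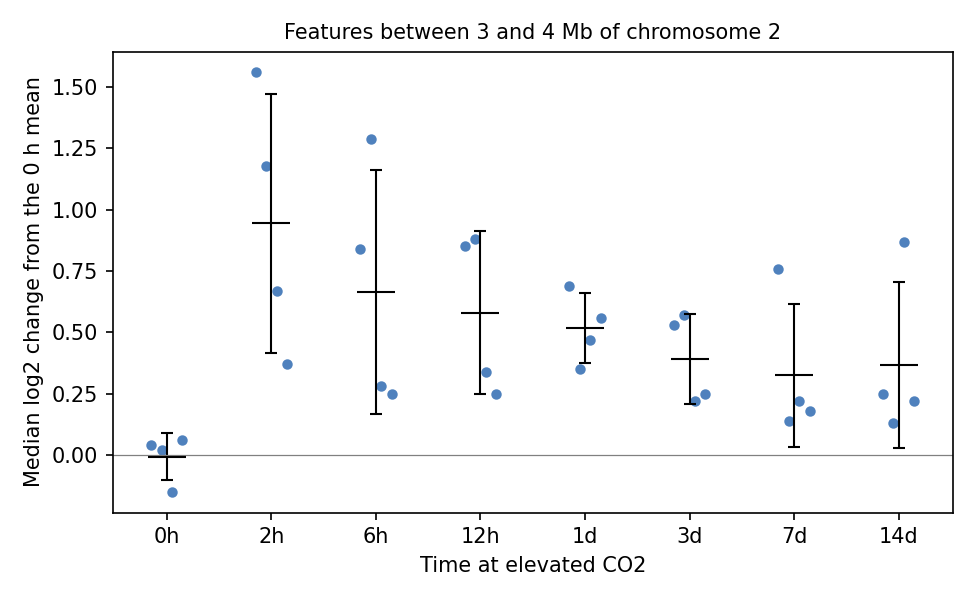
Median log2 change from the 0 h mean of the 229 features between 3 and 4 Mb of chromosome 2, per array (points), with the mean and SD of the 4 arrays (bars), by time at elevated CO2. The 28 exposed arrays lie above the highest 0 h array (0.06), and the 2 h arrays lie between 0.37 and 1.56.

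After 6 h and 12 h, ribosomal protein genes were among those that rose, and SUC6 and SUC8 had the largest falls of the named genes at 12 h. NUDT24 rose by 3.85 ± 0.65 at 6 h and 3.62 ± 0.65 at 12 h (SE, n = 4, adjusted p = 0.022 and 0.013). Its 0 h level was not well above background on most arrays, so the size of these rises is uncertain. The ribosomal proteins AT1G02830 (at least 1.95-fold and at least 2.22-fold), AT3G09680 (1.07 and 1.08) and AT5G59240 (1.01 and 0.78) rose at both times, and so did the putative sugar transporter AT5G18840 (1.56 and 1.75). The import protein AT1G18320 rose by 1.01 at 6 h. At 12 h the amino acid carrier UMAMIT14 rose by 2.25 ± 0.42 (adjusted p = 0.013), the beta-amylase BAM5 by 2.75, the transcription factor WRKY38 by 1.60 and AZI1, a defence gene, by 1.69. SUC6 and SUC8, sucrose carriers, fell by 3.50 ± 0.81 and 3.20 ± 0.71 at 12 h (adjusted p = 0.049 and 0.044). At 6 h 29 features rose and 2 fell, and at 12 h 81 rose and 15 fell. Transducin was enriched among rises at both times (hypergeometric adjusted p = 0.003 and 0.00087), and carbohydrate among falls at 12 h (3 of the 15 that fell, adjusted p = 0.014). Cytosolic ribosomal proteins had list medians of 0.28 and 0.34 (camera adjusted p = 6.9e-20 and 7.4e-29, but p = 0.45 at both times with the estimated correlation), with 3 members past the threshold at each time (6 and 10 adjusted over the list alone). Sugar-repressed genes had medians of -0.82 and -0.53 with none past the threshold, and sugar-induced genes 0.33 and 0.31, of which BAM5 rose at 12 h. Salicylic acid defence (0.39, with WRKY38 past the threshold), jasmonate response (0.51) and glucosinolate synthesis (0.22) had higher medians at 12 h, and none of these lists was called with the estimated correlation. With only the groups compared in the fit limma called 0 at 6 h and at 12 h (2544 and 4021 with an unadjusted p under 0.05), and the counts were 4 and 9 without slide 1 and 446 and 1004 with array weights. The count at 6 h was 0 without 0 h replicate 3, 0 h replicate 4, 6 h replicate 3 or 6 h replicate 4, 1 without 6 h replicate 1 and 9 without 0 h replicate 2. The count at 12 h was 0 without 0 h replicate 4 or 12 h replicate 3, 7 without 12 h replicate 2, 39 and 42 without 0 h replicates 3 and 1, 59 without 0 h replicate 2 and 54 without 12 h replicate 1, whose file name carries another number than its label. On slide 1 and slide 2 the ribosomal list median at 6 h was 0.21 and 0.30, and on slide 4 it was 0.30 at 12 h. On slide 4, which alone holds both 0 h and 12 h, salicylic acid defence turned to -0.24, jasmonate response stood at 0.07, glucosinolate synthesis at 0.40, sugar-repressed genes at -0.88 and sugar-induced genes at 0.17. At 6 h on slides 1 and 2 sugar-repressed genes stood at -0.33 and -0.09 and sugar-induced genes at 0.31 and 0.20, and with slide as a block sugar-repressed genes stood at -0.41 at 6 h and -0.22 at 12 h.

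After 1 d, ribosomal protein genes and flavonoid genes were among those that rose. NUDT24 rose by 3.05 ± 0.65 (adjusted p = 0.029), against a 0 h level not well above background on most arrays. AT5G10040 rose by 2.94 ± 0.56, AT3G29970 by 2.61 ± 0.62, UMAMIT14 by 2.43 ± 0.42, the transcription factor ERF71 by 2.18 ± 0.53 and the pyruvate decarboxylase AT4G33070 by 2.00 ± 0.49 (SE, n = 4). The anthocyanin genes LDOX (2.17, adjusted p = 0.041) and GSTF12 (1.83, adjusted p = 0.048) rose, with 7 of 19 flavonoid genes past the threshold adjusted over the list alone (camera p = 1.4e-06, but p = 0.48 with the estimated correlation). AT1G02830 rose at least 1.59-fold, and 10 of the 181 ribosomal proteins rose (104 adjusted over the list alone), with a median of 0.51 (camera p = 1.3e-38, but p = 0.35 with the estimated correlation). SUC6 fell by 3.36 ± 0.81 (adjusted p = 0.046), the photorespiratory aminotransferase GGT2 fell by 0.62 and the B-box gene BBX27 fell by 1.48. BAM5 (2.59), WRKY38 (1.61) and G6PD3 (0.74), on the starch, salicylic acid and nitrogen lists, rose as well. Cell division genes had a median of 0.39 with none past the threshold over all features. In all 138 features rose and 44 fell, and ribosomal (12 of 341) was enriched among rises (hypergeometric adjusted p = 0.00039). With slide as a block 6 features were called, where the 182 had a median size of 0.78 against 0.86 without it, and the ribosomal list median was 0.48. With only 0 h and 1 d in the fit limma called 0 (2233 with an unadjusted p under 0.05), and the count was 6 without slide 1 and 548 with array weights. The count was 68, 69, 0 and 0 without 0 h replicates 1 to 4, and 557, 545, 55 and 0 without 1 d replicates 1 to 4. Without 1 d replicate 3 the ribosomal list median was 0.36. On slide 4 the list medians at 1 d were 0.21 for ribosomal proteins, 0.26 for flavonoid genes and 0.17 for cell division genes, and with slide as a block the last stood at 0.09.

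**Figure D2:**
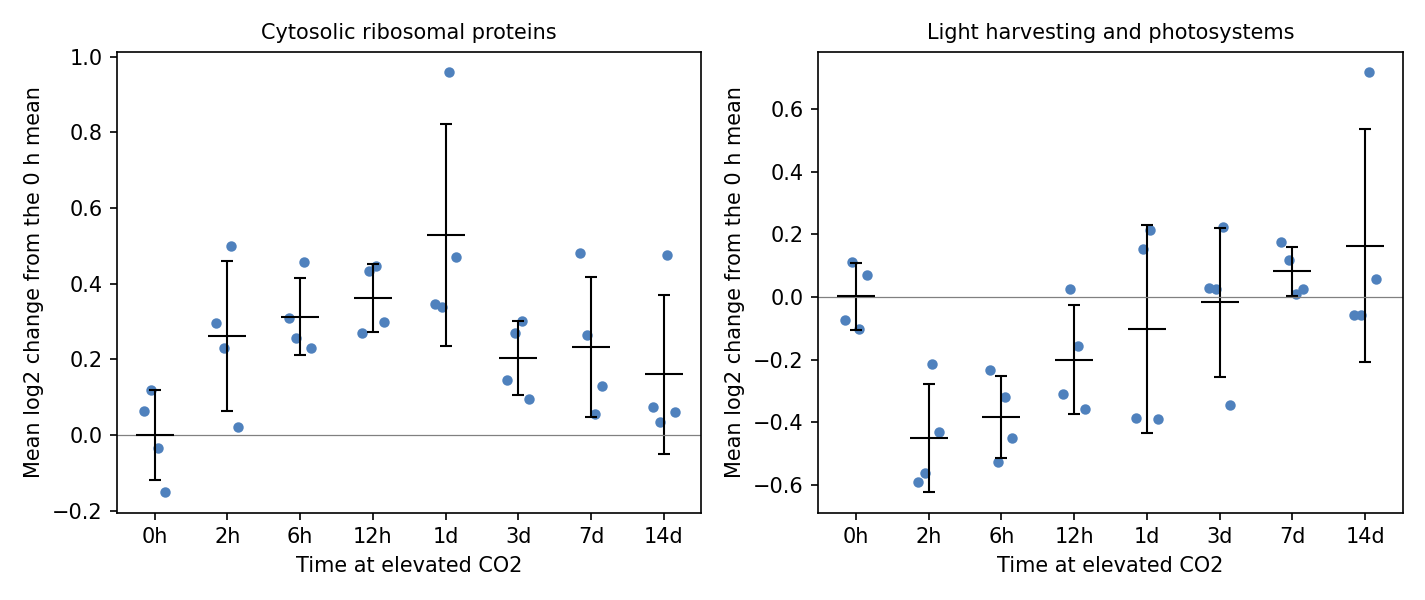
Mean log2 change from the 0 h mean of the cytosolic ribosomal proteins (left) and the light harvesting and photosystem genes (right), per array (points), with the mean and SD of the 4 arrays (bars), by time at elevated CO2. The group mean of the ribosomal proteins is highest at 1 d.

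After 3 d, 7 d and 14 d few genes passed the threshold. UMAMIT14 rose by 2.92 ± 0.42 at 3 d (adjusted p = 0.0036) and 2.79 ± 0.42 at 7 d (adjusted p = 0.0081). AT3G29970 rose by 3.39 ± 0.62 and 3.52 ± 0.62 at these times, and AT5G10040 (3.21) and the terpene synthase AT1G48800 (2.83) rose at 3 d (SE, n = 4). The hexosyl transferase AT5G37950 rose by 1.75 and AT1G07330 fell at least 1.16-fold at 7 d, with no 7 d array well above background. At 3 d 5 features rose and 0 fell, at 7 d 3 rose and 1 fell, and at 14 d 0 were called by limma, where 923 had an unadjusted p under 0.05 and the smallest adjusted p was 0.051. At 14 d other settings called 12 (quantile normalization), 4 (normexp), 15 (replicate block), 6 (slide block) and 109 (array weights). Lists called by camera with the preset correlation included cytosolic ribosomal proteins at 3 d, 7 d and 14 d (medians 0.19, 0.25 and 0.17, adjusted p = 1.9e-10, 4.2e-14 and 7.1e-09, but 0.62, 0.53 and 0.69 with the estimated correlation, and on single slides 0.08 and 0.50 at 3 d, 0.20 at 7 d and 0.02 and -0.10 at 14 d), heat shock and oxidative stress genes at 3 d (0.32), phosphate starvation genes at 7 d and 14 d (-0.54 and -0.59), iron deficiency genes at 14 d (-0.56), abscisic acid, cold and drought genes at 14 d (0.48) and flowering genes at 14 d (0.21), with no member past the threshold over all features. With the estimated correlation the adjusted p of these lists was 0.27 to 0.69. On single slides abscisic acid, cold and drought genes at 14 d stood at 0.71 and -0.33, phosphate starvation genes at -0.03 at 7 d and -0.72 and -0.80 at 14 d, iron deficiency genes at -1.19 and -0.99, flowering genes at 0.37 and 0.41 and heat shock genes at 3 d at 0.33 and 0.60. For iron deficiency at 14 d, 2 genes fell adjusted over the list alone, and for flowering 3 rose. With slide as a block 0 features were called at 3 d and at 7 d, where limma gave 1149 and 1281 features with an unadjusted p under 0.05 without the block. The features called at 3 d and 7 d had a median size of 2.92 and 2.27 without the block and 2.53 and 2.08 with it, and the residual df was 24 and 17. With only the groups compared in the fit limma called 0 at 3 d and at 7 d (1360 and 2633 with an unadjusted p under 0.05) and 1 at 14 d. At 3 d the count was 1 without 0 h replicate 2, 0 h replicate 3 or 3 d replicate 4, 2 without 0 h replicate 4 or 3 d replicate 1 and 3 without 3 d replicate 2 or 3 d replicate 3. At 7 d it was 1 without 0 h replicate 2 or 0 h replicate 3 and 0 without 7 d replicate 2, and at 14 d it was 3 without 14 d replicate 1.

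Short exposure differed from long exposure in light harvesting and flavonoid genes. The glucose-phosphate carrier GPT2 was higher by 1.86 ± 0.37 at 2 h to 12 h than at 3 d to 14 d (SE, 12 arrays against 12, adjusted p = 0.0058), and the anthocyanin regulators MYB90 and MYB75 were higher by 1.38 ± 0.30 and 1.28 ± 0.27. The germin-like gene AT3G05950 (at least 3.63-fold, 3 of 12 long exposure arrays well above background), AT1G02830 (at least 1.68-fold, 2 of 12), the copper dismutases CSD1 (0.90) and CSD2 (0.74), the cell wall gene XTH33 (1.00), PR5 (0.72) and the carrier OPT3 (0.63) were also higher after short exposure. Lower after short exposure were the antenna genes LHCA2 (-0.95), LHCA3 (-0.82) and LHCB4.2 (-0.70), the photosystem gene PSAD-2 (-0.76), the carbonic anhydrase CA2 (-0.69), the expansins EXPA8 (-1.09), EXPA1 (-0.56) and EXPA6 (-0.48), HSP90.1 (-0.72), HSP18.2 (-0.72), CBF3 (-0.76), FUL (-0.52), CDF1 (-0.46), GLN1;4 (-0.52), the endodermis gene CASP5 (-1.65) and AT3G29970 (-1.99). Of 28 light harvesting and photosystem genes 12 were lower over all features (19 adjusted over the list alone), with a median of -0.35 (camera p = 1.7e-11, but p = 0.45 with the estimated correlation). Flavonoid genes had 3 of 19 higher (8 adjusted over the list alone, median 0.50, camera p = 6e-06 and 0.52 with the estimated correlation), MYB90, MYB75 and 4CL3. Sugar-induced genes had 3 of 15 higher (GPT2, MYB90 and MYB75). In all 649 features were higher and 668 lower, 1317 of 24356. The words pentatricopeptide (43 of 389), helicase (20 of 138) and DEAD (10 of 45) were enriched among the 584 annotated genes higher after short exposure, and harvesting (11 of 15), photosystem (14 of 38) and chlorophyll (11 of 37) among the 614 lower (hypergeometric adjusted p = 9.9e-12, 9.9e-07 and 0.00021 for the higher, and 2.6e-11, 1.6e-09 and 4e-06 for the lower). Scan days were uneven: of 12 short exposure arrays 1, 8 and 3 were scanned on days 1, 2 and 3, and of 12 long exposure arrays 2, 1 and 9. With scan day as a block 683 features were called, 439 of them among the 1317, and with slide as a block 726, 408 of them among the 1317. The median size of the 1317 was 0.48 without a block, 0.42 with scan day and 0.41 with slide. The count was 829 without 2 h replicate 1, 714 without 3 d replicate 3 and 799 without 7 d replicate 2. Deviations fell with genomic span (rank correlation across annotated genes) in 7 d replicates 1 and 2 (-0.348 and -0.311). They also fell in 3 d replicate 3 (-0.273) and 14 d replicate 3 (-0.259). Among short exposure arrays only 6 h replicate 3 had a negative value (-0.181), and the other long exposure arrays had positive ones. This trend was not removed for this contrast, so an effect of transcript length on it was not tested. Of the sORFs 4.476% were called, against 5.417% of the annotated genes (odds ratio 0.818, Fisher's exact test, adjusted p = 0.832), among them NEW_TU_3968 (1.25) and NEW_TU_3100 (at least 1.93-fold lower, 6 of 12 short exposure arrays well above background).

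**Figure D3:**
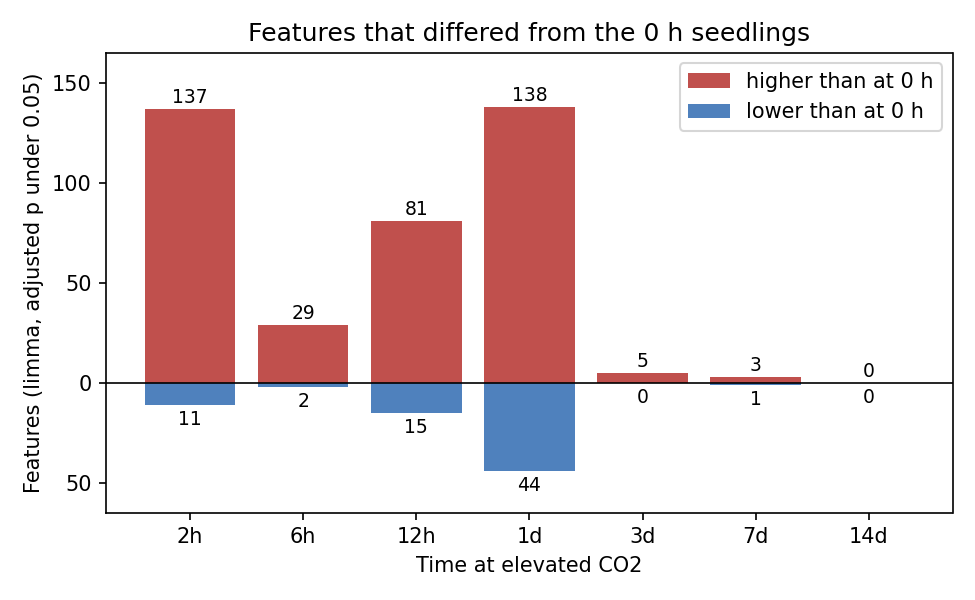
Numbers of features higher (above 0) and lower (below 0) than in the 0 h seedlings at each time, by limma with adjusted p under 0.05. The numbers of rises are 137, 29, 81, 138, 5, 3 and 0.

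Over the time course 145 features changed (F test, 137 annotated genes and 5 sORFs). AT4G30990 (adjusted p = 0.0023) was highest at 2 h (1.32) and near its 0 h level at 3 d (0.04). The import proteins AT1G18320 and MEE67 stood at 1.07 and 1.1 at 1 d and 0.12 and 0.10 at 14 d, and the nucleolar methylase FIB2 at 0.98 and 0.17. The transducin gene AT4G04940 stood at 1.00 at 12 h and the gene AT4G36580 at 0.87 at 2 h. UMAMIT14 (adjusted p = 0.0023) stood at 0.53 at 2 h and 1.74 at 14 d. The count was 81 and 73 without 0 h replicates 3 and 4, 94 and 91 without 2 h replicates 1 and 2, 257 without 1 d replicate 3, 88 without 7 d replicate 2 and 93 without 14 d replicate 4, and 67 with scan day as a block.

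**Figure D4:**
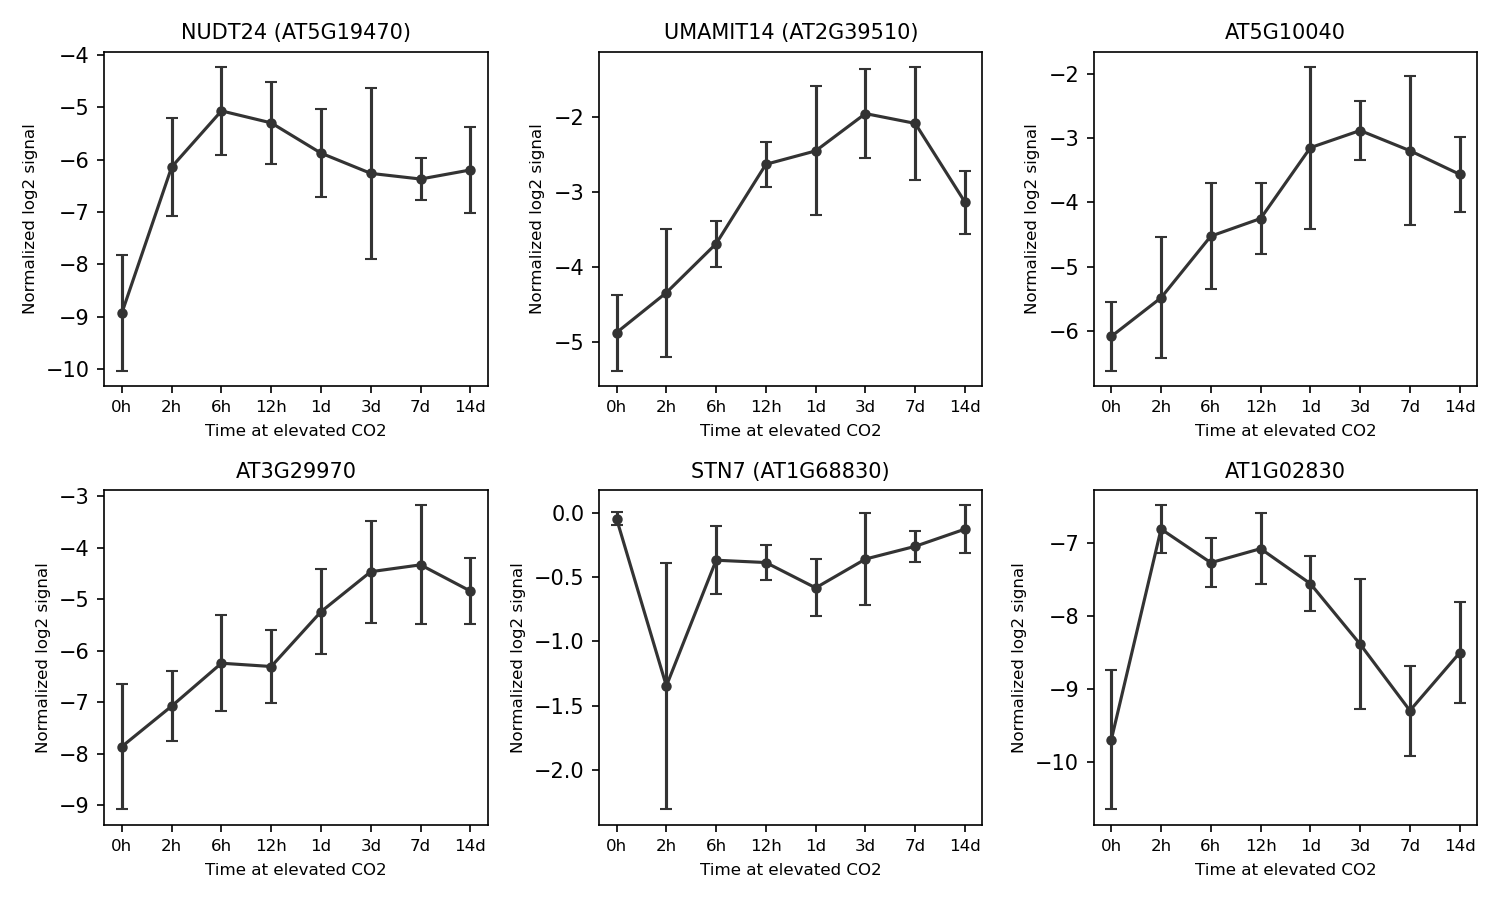
Normalized log2 signal (mean and SD of 4 arrays) of 6 named genes by time at elevated CO2. NUDT24 and AT1G02830 are higher from 2 h, AT5G10040, AT3G29970 and UMAMIT14 later, and STN7 is lower at 2 h.

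Responses at different times were compared through their log2 fold changes, which share the 4 controls. NUDT24, AT1G02830, AT3G09680 and AT5G59240 were among the 51 rises shared by 2 h and 12 h, where independent lists of these sizes would share 0.46. The correlation across features of 2 h with 6 h was 0.673 against 0.497 for simulated unchanged groups (covariance 0.0863 against 0.0503) and 0.290 with the controls split. For 2 h with 14 d it was 0.328 (covariance 0.0392) and 0.005 with split controls. Genes are not independent replicates, and part of each overlap comes from the shared controls. Arrays of 2 h and 6 h also share slides 2 and 7, while those of 2 h and 14 d share no slide. Deviations from the group means had a mean correlation of 0.194 on the same slide and -0.022 on different slides. Splitting the controls does not remove this, so slide and time cannot be told apart as the source of the difference between these correlations. The chamber had no effect past the threshold: limma called 0 features for the chamber, where 2393 had an unadjusted p under 0.05, and 0 for its interaction with exposure over the 7 times (F test), where 235 had one. The 1 d term of the interaction called 1 feature (smallest adjusted p = 0.00193), and the F test called 1 with slide as a random block.

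Of the 200 combinations of 25 lists and 8 comparisons, 73 were called by camera with the preset correlation, 45 higher and 28 lower, and 0 with the estimated correlation. Of these 73, 21 were no longer called with slide as a block and 13 with scan day as a block. Of the 63 called at single times, 14 had the opposite sign on at least 1 slide that holds both groups, 3 on every such slide and 1 with slide as a block. Starch genes at 12 h (BAM5 past the threshold), nitrogen assimilation genes at 1 d (G6PD3) and iron deficiency genes after short exposure (OPT3) were among the lists called higher. The lists of stomata and CO2 signalling, cell wall, leaf senescence, sulfur starvation, root marker and seed genes were called in no comparison by camera, though CA2 of the stomata list and EXPA8 and XTH33 of the cell wall list passed the threshold between short and long exposure.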

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

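The tests of slide effects, of the label letter, of matched ribosomal lists, of the span trend's rank correlation in 1 d replicate 3 and of a wrong label were chosen or written down after the values they rest on were seen, and the counts of splits were known when their bounds were written down. The tests that removed the span trend from the rises, from the chromosome 2 block and from 1 d replicate 3, and the regroupings within scan days, were written before their results were seen. Among groups of 4 arrays, 26 of 503 had an array far from the others, by the gap test of Dixon at the 95% level, and chance gives about 1 in 20 groups.

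A 75th percentile signal of 1447 in 14 d replicate 3 lay below the other 3 arrays (2851 to 3065). The median of the chromosome 2 block was 0.76 in 7 d replicate 1 and 0.87 in 14 d replicate 3, above the others of their groups (at most 0.22 and 0.25). Among named genes at 6 h, AT1G51380 was at -0.16 and AT3G09680 at -1.92 in replicate 1, and AT5G27120 at 1.72 in replicate 2 (normalized log2 signal). In 2 h replicate 4, CASP5 was at -6.49, GLN1;4 at -2.10, PR5 at -0.92 and EXPA8 at 2.54, each away from the other 3 arrays, and in 2 h replicate 3 AT1G60913 was at -7.89 and OPT3 at 1.99. At 12 h AT4G34690 (-8.04) and LHCB4.2 (1.3) stood apart in replicate 1, and NEW_TU_3749 (-7.98) and AT5G59240 (-0.97) in replicate 3. In 0 h replicate 2 AT2G17740 was at -4.40, and in 1 d replicate 4 SULTR1;3 was at -4.01. Later, AT3G09870 (-7.38) and XTH33 (-3.38) stood apart in 7 d replicate 3, EXPA8 (1.84) in 7 d replicate 1, PR5 (-1.81) in 3 d replicate 3 and EXPA6 (2.63) in 3 d replicate 1. In the 14 d group these were AT1G52820 (-0.87) in replicate 4, PSAD-2 (3.70) in replicate 3 and HSP18.2 (-1.56) in replicate 2. Single arrays of dim genes decide little, and the fit keeps all 4.

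Short and long exposure differed in 1317 features, and the response at 1 d differed between the chambers in 1 feature. Other splits of the arrays gave fewer calls. Of 35 splits of the 8 arrays, 1 gave as many as the real one at 2 h (148, highest other 0), 6 h (31, highest other 2), 12 h (96, 0), 1 d (182, 4), 3 d (5, 1) and 7 d (4, 1). At 14 d 35 of 35 gave the real 0. A share of 1 in 35 (0.0286) is the smallest that such splits can give at 1 time. The splits share the 4 controls, were not adjusted over the 7 times and ignore slide, so they do not exclude chance at single times. With slide as a block 6 were called at 1 d and 0 at 3 d and at 7 d. With only the groups compared in the fit 0 were called at each time up to 7 d. Of 100 drawn regroupings, 1 gave as many for short against long exposure (1317, highest other 1) and 1 for the F test (145, highest other 1). Short exposure arrays were mostly scanned on day 2 and long ones on day 3, and of 100 regroupings within scan days 1 gave as many as 1317 (highest other 151), which argues against scan day as the whole cause. With scan day as a block the count was 683, 439 of them among the 1317, and the median size of the 1317 was 0.42 against 0.48. For gene lists called with the preset correlation, adjusted within each comparison, chance cannot be excluded: 27 of 35 splits gave as many as the real 6 at 2 h (highest other 13), 15 as many as 10 at 6 h (14), 15 as many as 10 at 12 h (16), 9 as many as 10 at 1 d (14), 12 as many as 8 at 3 d (15), 9 as many as 9 at 7 d (16) and 14 as many as 11 at 14 d (14). For short against long exposure 15 of 100 gave as many as 11 (highest other 15).

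The rises at 2 h to 1 d (median log2 fold change 0.86 over 385 pairs of feature and time) were tested against slides and transcript length as the whole cause of their size. With slide as a block their median was 96.0% of that without it, and with each array's trend on genomic span removed it was 102.2%. These features were picked as rises in the fit of the same arrays without the block, which favours a kept size. Their median span (1593) was near that of all located features (1606), so removing a span trend could move them little. Neither value therefore decides on slide or transcript length. Of 10000 lists matched to the ribosomal proteins on span and signal, 0% had as high a median as theirs at the time where that share was largest. Ribosomal genes move together (estimated correlation 0.325) and genes drawn at random do not, so a deviation shared by arrays or slides could also give this. The share was 0% at 14 d as well, where the list median was 0.02 and -0.10 on single slides. Span and signal alone thus did not give such a median, but the draws do not decide on slide or array effects. The calls themselves depend on the slide block: at 1 d it gave 6, of which 3 were among the 182 without it, at 12 h it gave 93, of which 39 were among the 96, at 6 h it gave 43, of which 18 were among the 31, and at 2 h it gave 267, of which 112 were among the 148. The median size of the 182 at 1 d was 0.86 without the block and 0.78 with it (median SE 0.18 and 0.19), all in the same direction, and what ended single calls was not tested further, so single calls at these times stay open. A biological response to CO2 is a hypothesis that stays open with it.

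The rise of the chromosome 2 block at 2 h kept its direction, but not its size, across slides. Arrays of 2 h and 0 h on the same slide differed by 1.71 and 1.33 on slide 2 and by 0.61 on slide 5, and the lower block median of 2 h replicates 3 and 4 was 0.37 against at most 0.06 at 0 h, which argues against slide or label letter as the whole cause. Without each array's trend on genomic span the block median at 2 h was 98.2% of that with it. Rank correlations of the deviations with span were 0.043 to 0.103 at 0 h and 0.071 to 0.155 at 2 h, so removing the trend could move the block little. These values argue only against a linear trend on span, and other effects of transcript length were not tested. The 2 h replicates 1 and 2 (mean 1.37), both on slide 2, had a larger rise than replicates 3 and 4 (0.52), which lie on slides 5 and 7, and slide and label letter cannot be told apart as the source of that difference. A nuclear copy of mitochondrial sequence is known in this part of chromosome 2 in Col-0, where 21 annotated genes of the block are described as mitochondrial, and probes there may read mitochondrial transcripts as well as nuclear ones. A rise of mitochondrial transcripts is then a candidate explanation beside a rise of nuclear ones, and no value here parts the sources.

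The array of 1 d replicate 3 had a median correlation of 0.9549 with the others, where the next lowest had 0.9689. Its deviation fell with genomic span (rank correlation -0.36 across genes, which are not independent replicates), lower than on the other 31 arrays, though 7 d replicate 1 was close (-0.348) and was not apart. Removing each array's linear span trend left its median correlation at 0.9606, below that of the other arrays, so a linear trend is not the whole of it. The other arrays of its slide reached 0.9823, which argues against a slide effect. A wrong label stays open: its correlation was 0.9622 with the mean of its own group and at most 0.9671 with that of another, but 25 of the other 31 arrays were also nearer to another group's mean than to their own, so such a value does not decide. RNA of lower quality may explain it in part, and no biological explanation was tested.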

How the results depend on the processing

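Of 160 named gene values none changed direction under any alternative run, and within each scan day all 18, 107 and 97 values that could be formed kept their direction, but the rule that named these genes asked for arrays or time means on one side, which largely fixes this and supports nothing against a scan day effect. Of the 160, 88 no longer passed the threshold with slide as a block, 49 with scan day as a block, 113 with only the groups compared and 102 without slide 1, and of the 111 that rest on 0 h, 104 without 0 h replicate 4 and 92 without 0 h replicate 3. Counts of calls depended on the setting, and the cause was not tested except where fewer samples or features enter by construction. The array limits the precision of low genes, which lie near background. The blocks by scan day and label letter and the settings that leave out slide 1 (alone or with 1 d replicate 3) or the chromosome 2 block were chosen after seeing the data. The alternative of a mean over probes had nothing to change, since no feature has more than 1 probe, and camera was not run with slide as a random block.

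With quantile normalization, 56 features were called at 6 h (49 higher, 7 lower), 3 at 3 d and 12 at 14 d (4 and 8). With normexp these were 53 at 6 h (81.1% higher against 93.5%), 147 at 12 h, 306 at 1 d (64.1% higher against 75.8%), 1 at 3 d, 1 at 7 d and 4 at 14 d, and 228 over the time course. With the series matrix values they were 54 at 6 h, 3 at 3 d and 11 at 14 d. Among features differing between short and long exposure, quantile normalization called 61.9% higher and the series matrix 62.0%, against 49.3% with the 75th percentile. At 7 d quantile normalization and the series matrix each called 5 higher and 0 lower, against 3 and 1. With no filter the counts were 59 at 2 h, 10 at 6 h, 45 at 12 h, 68 at 1 d, 1 at 3 d, 2 at 7 d and 85 over the time course, and the odds ratios of sORFs were 1.07 at 2 h, 0.289 at 1 d and 0.472 for short against long exposure. With features well above background on all arrays, the counts were 51 at 6 h, 2 at 3 d, 2 at 7 d and 1 at 14 d, and the odds ratio at 1 d was 2.17.

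The chamber block left 2 at 7 d. The replicate block gave 66 at 6 h, 200 at 12 h, 606 at 1 d, 19 at 7 d, 15 at 14 d, 2094 for short against long exposure and 308 over the time course. Over the 7 times, deviations of same-numbered arrays had correlations with 0 h from -0.281 to 0.732. They averaged 0.137 over all groups against -0.046 for other numbers, and not every array correlated best with its own number. The highest, for replicate 1 at 6 h, 3 d and 14 d (0.668, 0.655 and 0.732), were all of arrays on slide 1, as is 0 h replicate 1. Replicate 1 at the other times, on other slides, had 0.091 to 0.18, though 6 h replicate 3, not on the slide of 0 h replicate 3, had 0.459. Pairing by number thus stays a hint that a shared slide may account for in large part. None of the lists called at 14 d lost its call with this block. The slide block gave 267 at 2 h, 6 at 1 d, 0 at 3 d, 0 at 7 d, 6 at 14 d and 726 for short against long exposure, where limma found 1149 and 1281 features with an unadjusted p under 0.05 at 3 d and 7 d without it. The features called without it had a median size of 2.92 at 3 d and 2.27 at 7 d, and of 2.53 and 2.08 with it (residual df 24 and 17). Slide as a random block gave 332 at 2 h, 132 at 6 h, 227 at 12 h, 286 at 1 d, 2 at 7 d, 10 at 14 d and 1 for the interaction with chamber, and an odds ratio of 1.73 at 1 d. Array weights gave 2458 at 2 h, 446 at 6 h, 1004 at 12 h, 548 at 1 d, 308 at 7 d, 109 at 14 d, 4293 for short against long exposure and 3747 over the time course, and an odds ratio of 0.800 for short against long exposure. These weights ran from 0.112 (1 d replicate 3) to 4.487 (2 h replicate 2), so arrays count unequally there. With only the groups compared in the fit, limma called 0 at each time up to 7 d and 1 at 14 d (2907, 2544, 4021, 2233, 1360 and 2633 with an unadjusted p under 0.05), and the odds ratio for short against long exposure was 0.757.

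Counting only features at least 2-fold changed left 55 at 2 h, 13 at 6 h, 39 at 12 h, 62 at 1 d and 95 for short against long exposure, with odds ratios of 2.57 at 1 d and 2.14 for short against long exposure. At an adjusted p under 0.01, 16 were left at 2 h, 0 at 6 h, 0 at 12 h, 2 at 1 d, 1 at 3 d, 1 at 7 d, 307 for short against long exposure and 41 over the time course, and the odds ratio at 2 h was 2.67. Camera with the estimated correlation called 0 lists in place of 73. In chamber A alone limma called 0 at 2 h, 6 h, 12 h, 3 d and 7 d, 1 at 1 d, 0 for short against long exposure and 0 over the time course, and the photorespiration list at 3 d had a median of 0.09. In chamber B alone it called 1 at 2 h, 0 at each later time up to 7 d, 0 for short against long exposure and 0 over the time course, with an odds ratio of 0 at 2 h and list medians at 14 d of -0.15 (Calvin-Benson cycle), -0.16 (light harvesting) and 0.00 (glucosinolate synthesis). Each chamber alone has 2 arrays per group. Scan day as a block gave 20 at 6 h, 2 at 3 d, 10 at 14 d, 683 for short against long exposure and 67 over the time course. The label letter as a block gave 69 at 6 h, 185 at 12 h, 467 at 1 d, 2 at 3 d, 9 at 14 d and 323 over the time course.

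Without slide 1 the counts were 12 at 2 h, 4 at 6 h, 9 at 12 h, 6 at 1 d, 2 at 3 d, 2 at 7 d, 3 at 14 d and 50 over the time course, with an odds ratio of 1.70 at 2 h. Without slide 1 and 1 d replicate 3 they were 97 at 2 h, 19 at 6 h, 55 at 12 h, 2 at 1 d, 2 at 3 d, 2 at 7 d and 2 at 14 d, and 1867 for short against long exposure. Without the chromosome 2 block 83 were called at 2 h, and the odds ratios were 0.255 at 2 h and 0.538 for short against long exposure. Leaving out 1 array at a time gave 13 to 245 at 2 h, 0 to 29 at 6 h, 0 to 77 at 12 h, 0 to 557 at 1 d, 1 to 7 at 3 d, 0 to 6 at 7 d, 0 to 3 at 14 d, 714 to 1718 for short against long exposure, 73 to 257 over the time course and 63 to 80 lists. The odds ratios ran from 1.56 to 6.07 at 2 h, 0.344 to 0.979 at 1 d and 0.595 to 1.11 for short against long exposure. The lists that changed direction were abscisic acid, cold and drought at 3 d (-0.03 without 3 d replicate 4, range -0.03 to 0.82), Calvin-Benson cycle at 14 d (-0.02, range to 0.24) and light harvesting at 14 d (-0.03, range to 0.23), the last pair without 14 d replicate 3.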

Other observations

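The tests of this part were chosen after the values were seen, except that the slide test and the regrouping within scan days were written before their results were known. Genes that respond to low oxygen had a higher mean at 1 d and later than at 0 h, though few passed the threshold. The alcohol dehydrogenase ADH1 stood at 1.15 at 1 d and 1.25 at 3 d, the haemoglobin HB1 at 1.91 and 1.63, the sucrose synthase SUS4 at 1.58 and 1.85, the gene AT5G39890 at 1.35 and 1.47 and FTM1 at 1.75 and 1.75 (log2 fold change against 0 h, n = 4). At 2 h these genes stood at 0.05, -0.20, -0.01, -0.07 and 0.27, and at 6 h at 0.01, 0.92, 0.65, 0.78 and 0.95. In a list of 27 such genes, 22 were not named by the rule, and of these 22 limma called 1 at 1 d and 0 at 3 d, 7 d and 14 d over all features. The mean shift of these 22 was 0.89 at 1 d, 1.01 at 3 d, 0.89 at 7 d and 0.69 at 14 d, against -0.13 at 2 h, 0.34 at 6 h and 0.21 at 12 h (SD 0.27 at 0 h). At 6 h 3 of 4 arrays lay above every 0 h array and 16 of the 22 genes were above their 0 h mean, so the time at which any rise began stays open.

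A hypothesis is that seedlings held longer at elevated CO2 had a stronger low-oxygen response. By an exact 2-sided permutation test of 4 arrays against 4, whose smallest possible p is 0.0286, the shift had p = 0.0286 at 1 d, 3 d and 14 d and 0.0857 at 7 d, the largest of those at 1 d, 3 d and 7 d, so that the asked p under 0.05 was missed at 7 d, and each adjusted p over the 7 times was at least 0.0667. For short against long exposure the mean was lower by 0.73 (value -0.73) and a permutation test of 12 arrays against 12 with 100000 draws gave p = 2e-04, with 22 of the 22 genes lower and 10 called by limma. Short and long exposure differ in their scan days, and a permutation test of these 12 arrays against 12 within scan days gave p = 0.002. A larger share of roots may raise such genes. The root marker list shifted by 29.7% as much at 3 d, where 85.7% of its members were higher, and by -0.22 at 14 d. Some of its genes also lie on nutrient lists, so its mean does not measure the root share, and this explanation stays open. With slide as a block the median of the 22 genes at 3 d was 99.0% of that without it. The oxygen around the seedlings was not measured here, and the age at which each exposure began differs between the times.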
